A study of Mus musculus with 20 samples.

How the data were processed

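Livers of 20 mice with diet-induced obesity and steatohepatitis were profiled by RNA sequencing, 10 given vehicle (HEC 1%) and 10 given S217879 (30 mg/kg, by mouth, once daily) for 8 weeks. Groups were taken from the treatment label of each sample. Per the labels' protocols, total RNA was extracted with a lipid tissue kit and libraries were made with a stranded mRNA kit that captures polyadenylated RNA. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 were used with the build GRCm38, but the role and settings of each, the gene annotation, the use of strand and the handling of reads that match several genes are not given in the sources used here. The deposited table holds TPM values made by the authors, 49315 genes by 20 libraries, and each library sums to 1000000 over all genes of the table. TPM divides by gene length and by the library's own total, so it keeps no depth. A gene that takes a large share of a library lowers all others in it, and very short gene models such as Gm23935 (57 nt) get high values from few reads. The number of reads per library is therefore unknown, and precision is given as the spread between animals alone.

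Each column was matched to a sample through the animal number that its labels give, and 0 columns were left unmapped. The labels number every animal separately, with no number shared between the groups, so the libraries were treated as separate animals and no pairing was used. No pair of libraries held identical values (0 pairs). Of the gene identifiers, 48970 were given a symbol from a table of Ensembl identifiers, and 49056 were found in the GENCODE M21 annotation of GRCm38, from which coordinates, exons and overlaps were taken. All 13036 genes at 0 in every library were left out.

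The tests were fixed before the data were examined. Values were taken as log2(TPM + 0.5), and genes with a mean of at least 1 TPM over all 20 libraries were kept (13401). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust, Benjamini-Hochberg adjusted p under 0.05), with group as the only term. Fold changes are on the log2(TPM + 0.5) scale, which understates changes of low genes. For 39 gene lists fixed beforehand, covering NRF2 targets, drug metabolism, fibrosis, liver cell types, inflammation, lipid, bile acid and sugar metabolism, stress, cell cycle, sex bias, zonation, clock and possible contaminating tissues, the members past the threshold were counted over all genes and adjusted over the list alone. The 37 lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), adjusted over the lists. In the list of 24 NRF2 core targets 22 members reached the minimum. Where the text says that a list or gene rose or fell, it passed this test as deposited. A list score is the mean over tested members of log2 values centred per gene. Scores were related within groups by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, 6 relations in all.

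The genes named were chosen by a rule fixed before the data were examined. It takes 16 genes of interest in any case, then the 12 highest and 12 lowest log2 differences among called genes with at least 9 of 10 S217879 libraries beyond the vehicle median, and of each list the 2 members that rose most and the 2 that fell most (or the 2 most abundant where none was called). Not every gene so chosen is described. Predicted and clone-named models were passed over, 2 among the highest and 2 among the lowest. A few other genes are named after their values were seen: Osgin1, Akr1b8, Ccn2 and Col14a1 as the exceptions of their lists, Adipoq, Plin1 and Lep as fat cell genes, the 4 rRNA-type genes, and the genes of the closing section where it says so.

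The same steps were tested on simulated data with the means and residual spread of the 13401 genes of this comparison. Of genes changed by 0.5 on the log2 scale 70.1% were recovered, of those changed by 1 97.0%, and of those changed by 2 98.5%, with 11 of 13164 unchanged genes called. A shifted list was called and 0 of 36 other lists were. Genes were simulated as independent of each other and without scale differences between libraries. The simulation therefore does not measure false list calls among genes that vary together.

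Alternatives planned beforehand were pseudocounts of 0.1 and 1, minimum mean TPM of 0.1 and 5 or none, quantile normalization, median-of-ratios scaling, rescaling without mitochondrially encoded genes or without the 20 genes of highest mean TPM, eBayes with neither trend nor robust, array weights, leaving out each library in turn, a Wilcoxon rank-sum test per gene (exact, ties included), camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were rescaling without the 4 rRNA-type genes, leaving out vehicle replicates 6 and 7 together, camera with an estimated correlation after rescaling, and median-of-ratios scaling for the relations. Counts were also recomputed for 99 other random splits of the libraries into 10 and 10. Within each group of 10, the gap of the highest or lowest library was taken as a share of the range on the log2 scale. It was compared with Dixon's critical value of 0.466. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.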

Results

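Liver RNA was sequenced from 20 mice with diet-induced obesity and steatohepatitis, kept on the AMLN diet, a diet rich in fat, fructose and cholesterol that produces fatty liver with inflammation and scarring. Of these, 10 received the vehicle hydroxyethylcellulose (HEC, 1%) and 10 received S217879 by mouth at 30 mg/kg once daily, both for 8 weeks. By the title of the series, S217879 disrupts the binding of the transcription factor NRF2 to its repressor KEAP1, and the question is whether this resolves steatohepatitis and reduces fibrosis. The only comparison of the design is S217879 against vehicle, with 1 library per separately numbered animal. The table gives values in TPM (a gene's length-scaled share of its library) for 49315 genes, and each library sums to 1000000, so that the number of reads behind a value is unknown and no counting interval can be given. A library had between 24659 and 27744 genes above 0.

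Livers of mice given S217879 had higher levels of genes of antioxidant defence, glutathione conjugation and drug metabolism, and lower levels of genes of extracellular matrix, macrophages, inflammation, cholesterol synthesis and fatty acid synthesis. These directions rest on camera with its preset correlation, and each of the 24 list calls was lost with an estimated correlation (adjusted p from 0.0555 to 0.6914). Nqo1, a quinone reductase and classical NRF2 target, rose from 14.6 ± 3.52 to 102 ± 13.9 TPM (SD, n = 10 each), 6.92-fold on the log2(TPM + 0.5) scale. Col1a1, the main fibrillar collagen chain of scar tissue, fell from 58.4 ± 11.5 to 23.9 ± 6.53 TPM, and Trem2, a receptor of lipid-associated macrophages, fell from 8.59 ± 1.59 to 4.03 ± 1.46 TPM. Fads1, the delta-5 fatty acid desaturase, fell from 409 ± 88.0 to 62.1 ± 40.1 TPM.

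The groups were separate in a principal component analysis once a scale factor per library was removed (median-of-ratios scaling), where the first component held 46.6% of the variance. Vehicle libraries lay between -34.30 and -16.81 on it and S217879 libraries between 8.37 and 32.62, with S217879 replicate 9 closest to the vehicle group. Pairs of libraries correlated at 0.976 to 0.991 within vehicle, 0.974 to 0.991 within S217879 and 0.941 to 0.984 between the groups (Pearson's r across genes, which are not independent replicates). A single small-RNA gene model of 57 nt, Gm23935, took 24.2% ± 11.2 of all TPM in vehicle and 19.1% ± 5.58 in S217879 (SD, n = 10 each). Together with Gm24270, Gm42418 and Mir6236, here called the 4 rRNA-type genes, it took 30.0% ± 13.6 in vehicle and 24.0% ± 6.78 in S217879, a difference within the spread between animals (p = 0.2465, permutation test, two-sided). Vehicle replicates 6 and 7 stood apart with 58.2% and 50.7%, which leaves a smaller share of the total for the sum of all other genes. Mitochondrially encoded genes took 6.29% ± 1.37 in vehicle and 7.69% ± 1.24 in S217879 (p = 0.0179, permutation test, two-sided).

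**Figure D1:**
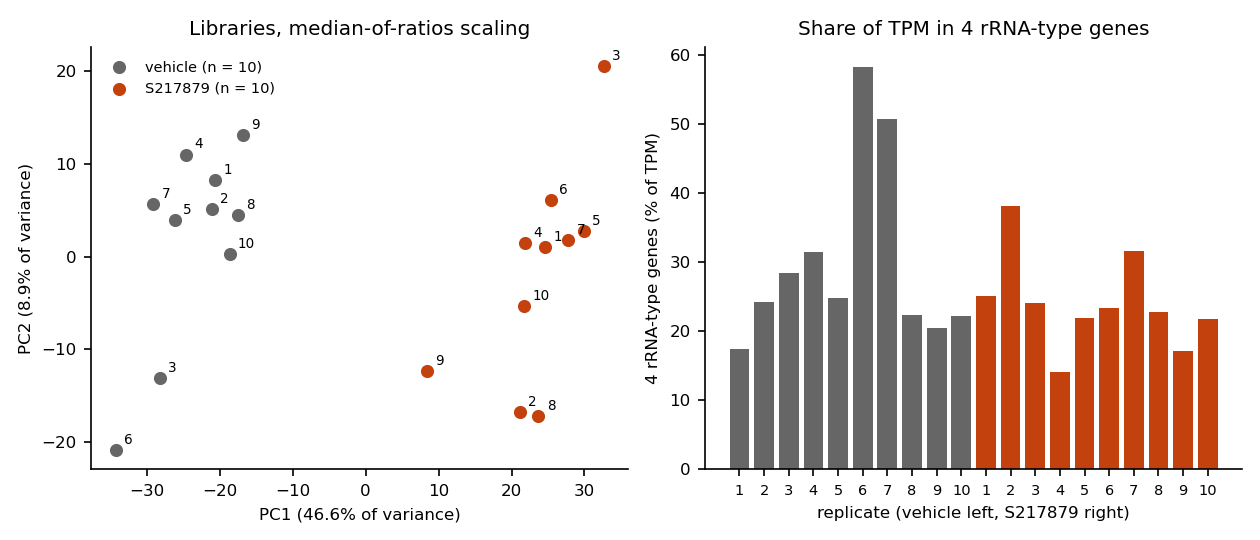
Left, the 20 libraries on the first and second principal components of log2 values with median-of-ratios scaling (axes in component units, numbers are replicates), with S217879 replicate 9 at 8.37 on PC1 and all other S217879 libraries further to the right. Right, the percentage of TPM in the 4 rRNA-type genes per library, highest in vehicle replicates 6 (58.2%) and 7 (50.7%).

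Of 13401 genes with a mean of at least 1 TPM, 813 were higher and 3151 lower in S217879 (limma, Benjamini-Hochberg adjusted p under 0.05), so that 79.5% of the calls were lower. Without vehicle replicate 6, 5194 genes were lower. With median-of-ratios scaling 3561 were higher and 3634 lower, 50.5% lower, and these calls held all 813 of the higher genes and 3026 of the lower ones. The split became more uneven in other alternatives: 965 higher and 8023 lower with array weights and, in 2 alternatives chosen after seeing the data, 1010 and 8576 when TPM was rescaled without the 4 rRNA-type genes and 747 and 7307 without vehicle replicates 6 and 7. The division into higher and lower therefore depends on the scale chosen for the libraries: the median log2 difference over all tested genes was -0.12 as deposited and -0.01 after this scaling, a shift of 0.11. List medians are given below as deposited and relative to the median of all genes. At least 2-fold changes were called for 370 genes, 165 higher and 205 lower, against 199 higher and 151 lower with median-of-ratios scaling. The groups did not overlap at all for 500 genes (3.73%, where chance gives 0.0011%).

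Of 22 tested core targets of NRF2, 19 rose and 0 fell (19 and 0 adjusted over the list alone). The core target list had a median log2 difference of 1.16 (1.28 relative to all genes), and camera gave adjusted p = 7.18e-36 (adjusted p = 0.0555 with an estimated correlation). Cbr3, a carbonyl reductase, rose from 8.25 ± 1.83 to 524 ± 149 TPM (log2 difference 5.87, SE 0.16, adjusted p = 1.69e-23 by limma, higher in 10 of 10 animals than the vehicle median). Gpx2, a glutathione peroxidase, rose from 0.43 ± 0.16 to 33.1 ± 11.3 TPM, and Abcc4, an efflux pump, from 3.03 ± 0.78 to 129 ± 39.1 TPM. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose from 185 ± 49.5 to 681 ± 170 TPM, while its modifier subunit Gclm rose from 66.4 ± 14.3 to 98.8 ± 9.74 TPM. Srxn1, sulfiredoxin, rose from 64.0 ± 12.3 to 215 ± 48.3 TPM. Hmox1, heme oxygenase 1 and a much used NRF2 readout, was at 50.1 ± 9.07 TPM in vehicle and 42.7 ± 9.02 TPM in S217879 (log2 difference -0.23, adjusted p = 0.1629). Over the 33 alternative settings its adjusted p ran from 0.0026 to 0.4322, with lower values and never a higher one. Osgin1 and Akr1b8, named because they are the other members that did not pass, had log2 differences of 0.30 and -0.06. Nfe2l2, which encodes NRF2, fell from 53.4 ± 9.53 to 28.5 ± 4.91 TPM (log2 difference -0.89, SE 0.12, adjusted p = 3.08e-07, lower in 10 of 10). Keap1 was at 29.9 ± 5.36 and 32.4 ± 3.71 TPM (adjusted p = 0.4156), and passed the threshold in 2 of 33 alternatives, median-of-ratios and quantile scaling, in the range of 2.27e-04 to 0.8860.

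**Figure D2:**
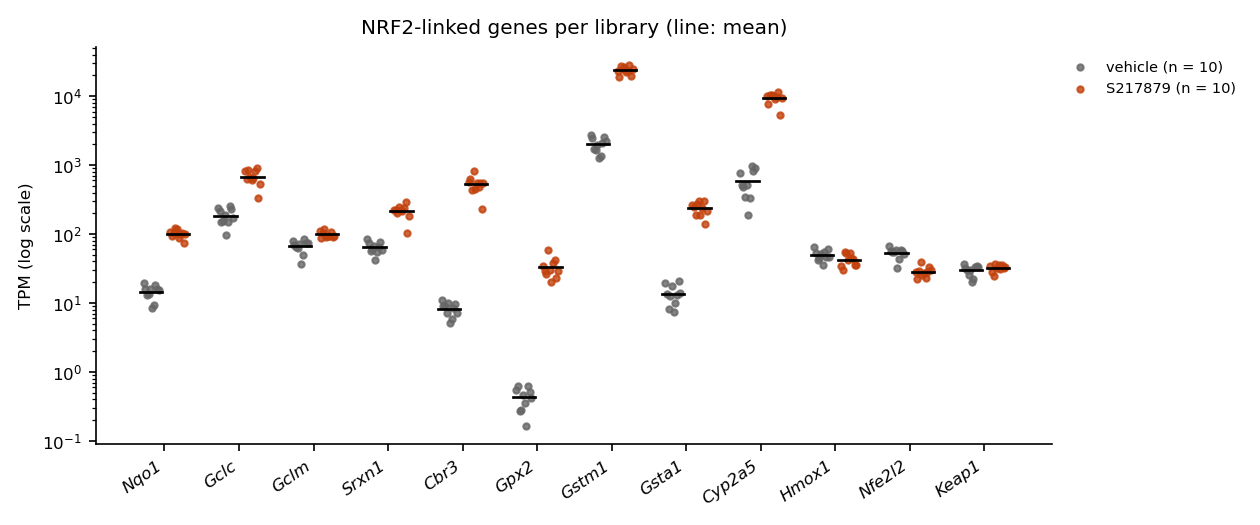
TPM (log axis) of 12 genes in each of the 20 libraries, vehicle and S217879, with lines at the mean of 10 libraries. Nqo1, Gclc, Gclm, Srxn1, Cbr3, Gpx2, Gstm1, Gsta1 and Cyp2a5 were higher in S217879, Nfe2l2 was lower, and Hmox1 and Keap1 did not pass the test as deposited.

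Glutathione S-transferases, which couple glutathione to electrophiles, rose in 14 of 21 tested members and fell in 1 (15 and 1 adjusted over the list alone). The transferase list had a median log2 difference of 1.20 (1.31 relative to all genes), and camera gave adjusted p = 2.58e-25 (adjusted p = 0.1267 with an estimated correlation). Gstm1 rose from 2013 ± 505 to 23954 ± 3064 TPM, which made it one of the most abundant liver transcripts of the treated mice. Gsta1 rose from 13.6 ± 4.55 to 236 ± 52.2 TPM, Gsta2 from 34.96 ± 13.3 to 406 ± 66.3 TPM and Gstm3 from 304 ± 83.7 to 3093 ± 747 TPM. Gstm5 was the member that fell, from 11.99 ± 2.17 to 6.73 ± 1.505 TPM. The Gsta and Gstm genes are close paralogs, and how reads shared between such copies were assigned is not given in the sources used here, so values of single members are uncertain.

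Other enzymes of xenobiotic and carbonyl metabolism rose as well. Among UDP-glucuronosyltransferases and sulfotransferases, 15 of 24 rose and 4 fell (17 and 4 adjusted over the list alone). Glucuronidation and sulfation genes had a median log2 difference of 0.56 (0.68 relative to all genes), and camera gave adjusted p = 1.71e-12 (adjusted p = 0.4154 with an estimated correlation). Array weights brought this median to 0.317. Ugt1a9 rose from 11.4 ± 3.10 to 103 ± 16.6 TPM and Ugt2b35 from 81.5 ± 19.4 to 343 ± 71.0 TPM. By contrast, Sult1a1 fell from 272 ± 52.2 to 129 ± 38.6 TPM and Sult1c2 from 5.94 ± 1.11 to 3.57 ± 0.92 TPM. Genes of the Ugt1a locus share exons, which leaves their single values uncertain. In aldehyde and carbonyl metabolism, 15 of 30 rose and 4 fell (17 and 4 adjusted over the list alone). Carbonyl metabolism genes had a median log2 difference of 0.40 (0.51 relative to all genes), and camera gave adjusted p = 1.94e-12 (adjusted p = 0.4967 with an estimated correlation). That median was 0.205 without vehicle replicates 6 and 7, 0.213 with array weights and 0.253 with TPM rescaled without the 4 rRNA-type genes. Cbr1 rose from 116 ± 25.4 to 1001 ± 174 TPM and the carboxylesterase gene Ces2c from 35.4 ± 10.5 to 172 ± 30.1 TPM. Aldh3a2 fell from 388 ± 90.3 to 238 ± 43.1 TPM and Ces3a from 825 ± 245 to 551 ± 107 TPM. The Ces3a call was lost with no filter on low values (adjusted p = 0.0684, with 1.84e-07 to 0.0684 over 33 alternatives). Of 10 genes of the pentose phosphate pathway and NADPH supply, 4 rose and 0 fell (5 and 0 adjusted over the list alone, 9 and 0 with median-of-ratios scaling). The pentose phosphate list had a median log2 difference of 0.25 (0.37 relative to all genes), and camera gave adjusted p = 8.73e-06 (adjusted p = 0.4440 with an estimated correlation). Its median was 0.120 with TPM rescaled without the 4 rRNA-type genes and 0.137 without vehicle replicates 6 and 7. Pgd rose from 26.3 ± 4.56 to 53.5 ± 11.3 TPM and Tkt from 59.0 ± 10.5 to 97.3 ± 12.2 TPM.

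Targets of the xenobiotic receptors CAR and PXR went in both directions. Of 14, 5 rose and 2 fell (5 and 2 adjusted over the list alone). Cyp2b9 rose from 31.0 ± 16.6 to 99.4 ± 51.5 TPM and Ces2a from 104.6 ± 38.9 to 236 ± 24.6 TPM, while Slco1a4 fell from 15.7 ± 4.21 to 4.12 ± 1.47 TPM and Cyp3a11 from 1176 ± 402 to 519 ± 137 TPM. The list median of 0.17 (relative 0.29) passed camera at an adjusted p of 0.0179 (adjusted p = 0.6475 with an estimated correlation) and turned to -0.01 without vehicle replicates 6 and 7 (0.087 without replicate 6 alone and 0.113 without replicate 7 alone). It passed in 30 of 37 alternatives, with adjusted p from 0.0020 to 0.6475, and did not pass with median-of-ratios scaling (adjusted p = 0.1997). Of 5 targets of the aryl hydrocarbon receptor, Cyp1a2 rose from 149 ± 57.9 to 1411 ± 384 TPM and Cyp1a1 from 0.41 ± 0.13 to 2.75 ± 0.76 TPM. Cyp1b1 and Nfe2l2 fell (2 rose and 3 fell adjusted over the list alone). The list did not pass camera (adjusted p = 0.1546, median -0.28 but mean 0.68). The coumarin hydroxylase Cyp2a5 rose from 585 ± 267 to 9436 ± 1730 TPM. Its paralog Cyp2a4 on the same chromosome (GRCm38 chromosome 7, 26307169 to 26315088, against 26835305 to 26843548 for Cyp2a5) rose from 15.3 ± 7.29 to 905 ± 281 TPM. Its log2 difference was 5.90 (SE 0.25, adjusted p = 2.44e-13). Cyp2a4 was at 3.07% ± 1.73 of Cyp2a5 in vehicle and 9.58% ± 2.30 in S217879.

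Matrix genes fell almost throughout. Of 36 tested genes of matrix and fibrosis, 0 rose and 34 fell (0 and 35 adjusted over the list alone). The matrix list had a median log2 difference of -0.71 (-0.59 relative to all genes), and camera gave adjusted p = 2.04e-15 (adjusted p = 0.4154 with an estimated correlation). Col3a1, the second fibrillar collagen, fell from 58.5 ± 13.2 to 27.6 ± 4.89 TPM (log2 difference -1.056, SE 0.13, adjusted p = 1.26e-08, lower in 10 of 10). Timp1, an inhibitor of matrix metalloproteinases, fell from 9.07 ± 1.89 to 4.22 ± 0.72 TPM. Mmp12, the macrophage metalloelastase, fell from 10.9 ± 2.09 to 3.88 ± 1.09 TPM. Ccn2 and Col14a1, named as the members that did not pass, had log2 differences of 0.12 and -0.29. Of 14 markers of activated stellate cells and myofibroblasts, 0 rose and 12 fell (0 and 14 adjusted over the list alone). Activated stellate markers had a median log2 difference of -0.40 (-0.28 relative to all genes), and camera gave adjusted p = 1.95e-04 (adjusted p = 0.4967 with an estimated correlation). Spon2 fell from 14.03 ± 2.93 to 5.57 ± 1.08 TPM and Mfap4 from 4.46 ± 1.27 to 2.37 ± 0.95 TPM. The smooth muscle actin gene Acta2 fell from 6.12 ± 1.70 to 4.73 ± 0.77 TPM at an adjusted p of 0.0491, a call kept in 14 of 33 alternatives (adjusted p from 0.0031 to 0.3236) and lost with median-of-ratios scaling. It was also lost without each of vehicle replicates 1, 2, 4, 5 and 9 and S217879 replicates 1, 3, 5, 6, 7, 8 and 9 (adjusted p from 0.0524 to 0.1242). Markers of quiescent stellate cells did not pass as a list (adjusted p = 0.2092), with 6 of 11 members lower (7 adjusted over the list alone). Rgs5 fell from 25.7 ± 6.01 to 18.4 ± 6.69 TPM and Reln from 10.99 ± 1.96 to 7.55 ± 0.87 TPM. The Rgs5 call was lost with no filter on low values (adjusted p = 0.0609, with 8.37e-06 to 0.0609 over 33 alternatives).

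Markers of lipid-associated and monocyte-derived macrophages, the cells that gather around dying fat-laden hepatocytes, fell in 18 of 21 tested members and rose in 1 (18 and 1 adjusted over the list alone). These macrophage markers had a median log2 difference of -0.85 (-0.74 relative to all genes), and camera gave adjusted p = 2.62e-09 (adjusted p = 0.4154 with an estimated correlation). Cd63 fell from 123 ± 24.0 to 44.5 ± 13.4 TPM, and Adgre1, which encodes F4/80, from 31.2 ± 7.32 to 20.1 ± 3.43 TPM. Lpl, lipoprotein lipase, was the member that rose, from 29.3 ± 4.92 to 47.7 ± 7.58 TPM. Kupffer cell markers, those of the resident liver macrophages, did not pass as a list (camera adjusted p = 0.2013, median -0.25), with 1 of 14 higher and 4 lower (1 and 4 adjusted over the list alone). Among these, the iron exporter gene Slc40a1 rose from 33.0 ± 8.51 to 45.9 ± 5.99 TPM, while C1qa fell from 225 ± 41.2 to 141 ± 27.6 TPM. C6, which is also in the list of male-biased liver genes, fell from 91.2 ± 25.3 to 28.9 ± 10.3 TPM. Inflammatory cytokines and chemokines fell in 17 of 24 members, with 0 rising (17 and 0 adjusted over the list alone). The cytokine list had a median log2 difference of -0.49 (-0.37 relative to all genes), and camera gave adjusted p = 8.73e-06 (adjusted p = 0.4967 with an estimated correlation). Ccl2, a monocyte attractant, fell from 7.46 ± 1.82 to 4.96 ± 0.89 TPM, Cxcl14 from 11.96 ± 2.33 to 5.15 ± 0.83 TPM and Il1rn from 4.58 ± 0.66 to 2.35 ± 0.48 TPM. Antigen presentation genes fell in 14 of 15 members with 0 rising (14 and 0 adjusted over the list alone). Antigen presentation as a list had a median log2 difference of -0.58 (-0.46 relative to all genes), and camera gave adjusted p = 4.67e-05 (adjusted p = 0.5889 with an estimated correlation). H2-Eb1 fell from 319 ± 63.8 to 194 ± 36.6 TPM and Cd74 from 624 ± 118 to 393 ± 54.6 TPM. Interferon response genes fell in 10 of 24 members with 0 rising (15 and 0 adjusted over the list alone). The interferon list had a median log2 difference of -0.35 (-0.23 relative to all genes), and camera gave adjusted p = 0.0076 (adjusted p = 0.6880 with an estimated correlation). Quantile normalization brought the median to -0.189. The list call was lost without vehicle replicates 6 and 7 (adjusted p = 0.0581, with 1.61e-04 to 0.7393 over 37 alternatives). Usp18 fell from 10.3 ± 1.95 to 4.94 ± 1.28 TPM and Ifit2 from 7.24 ± 0.95 to 4.42 ± 1.13 TPM. None of 15 markers of T, NK and B cells passed (0 adjusted over the list alone, camera adjusted p = 0.8750), with Ighm at 92.4 ± 128 and 57.5 ± 50.8 TPM and Ccl5 at 11.8 ± 4.68 and 10.04 ± 4.70 TPM. Only 4 neutrophil markers reached the expression minimum, too few for the list test. Of these, 2 fell and 0 rose (2 and 0 adjusted over the list alone), Lcn2 from 80.8 ± 15.6 to 42.4 ± 27.0 TPM and Csf3r from 4.62 ± 0.82 to 2.77 ± 0.40 TPM.

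Markers of the other liver cell types moved apart from each other. Sinusoidal endothelial markers rose in 6 of 16 members and fell in 2 (7 and 2 adjusted over the list alone). Endothelial markers had a median log2 difference of 0.15 (0.27 relative to all genes), and camera gave adjusted p = 0.0072 (adjusted p = 0.6880 with an estimated correlation). The median was 0.072 without vehicle replicate 6, 0.098 without vehicle replicate 7, 0.005 without both and 0.011 when TPM was rescaled without the 4 rRNA-type genes. Lyve1 rose from 10.95 ± 2.68 to 19.9 ± 3.33 TPM and Gpr182 from 16.2 ± 3.69 to 21.7 ± 3.34 TPM. The members that fell were Vwf, from 2.39 ± 0.41 to 1.53 ± 0.24 TPM, and Cd34, from 2.07 ± 0.50 to 1.29 ± 0.52 TPM, both better known from the endothelium of larger or remodelled vessels. Cholangiocyte and ductular markers fell in 6 of 12 members with 0 rising (6 and 0 adjusted over the list alone). Ductular markers had a median log2 difference of -0.47 (-0.35 relative to all genes), and camera gave adjusted p = 0.0371 (adjusted p = 0.6880 with an estimated correlation). This list call was lost without vehicle replicate 5 (adjusted p = 0.0501), vehicle replicate 6 (0.1287), S217879 replicate 6 (0.0709) or S217879 replicate 10 (0.0523), in a range of 3.02e-04 to 0.7393 over 37 alternatives. Spp1, also a macrophage marker, fell from 286 ± 68.6 to 144 ± 52.6 TPM and Epcam from 8.30 ± 2.88 to 5.17 ± 1.94 TPM. The Epcam call was kept in 22 of 33 alternatives (adjusted p from 3.69e-04 to 0.0618), and lost without each of vehicle replicates 2, 3, 5, 8, 9 and 10 and S217879 replicates 3, 5, 6, 7 and 10 (0.0501 to 0.0618). Hepatocyte identity genes did not pass as a list (camera adjusted p = 0.3464), with 2 of 22 higher and 3 lower (2 and 3 adjusted over the list alone, 9 and 3 with median-of-ratios scaling). Ttr rose from 4741 ± 1227 to 6514 ± 811 TPM and Apoa2 from 15348 ± 3678 to 20294 ± 2544 TPM, while Apoa1 fell from 9219 ± 2072 to 5759 ± 1807 TPM and Ahsg from 5600 ± 1187 to 3828 ± 783 TPM. The Apoa2 call was lost with quantile normalization (log2 difference 0.06, adjusted p = 0.6775) and without S217879 replicate 5 (adjusted p = 0.0573), in a range of 3.20e-06 to 0.6775. Blood cell transcripts did not pass (0 of 6, also adjusted over the list alone; camera adjusted p = 0.1272), with Hbb-bs at 111 ± 24.5 and 186 ± 135 TPM and Hba-a1 at 70.7 ± 15.9 and 101 ± 65.2 TPM.

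**Figure D3:**
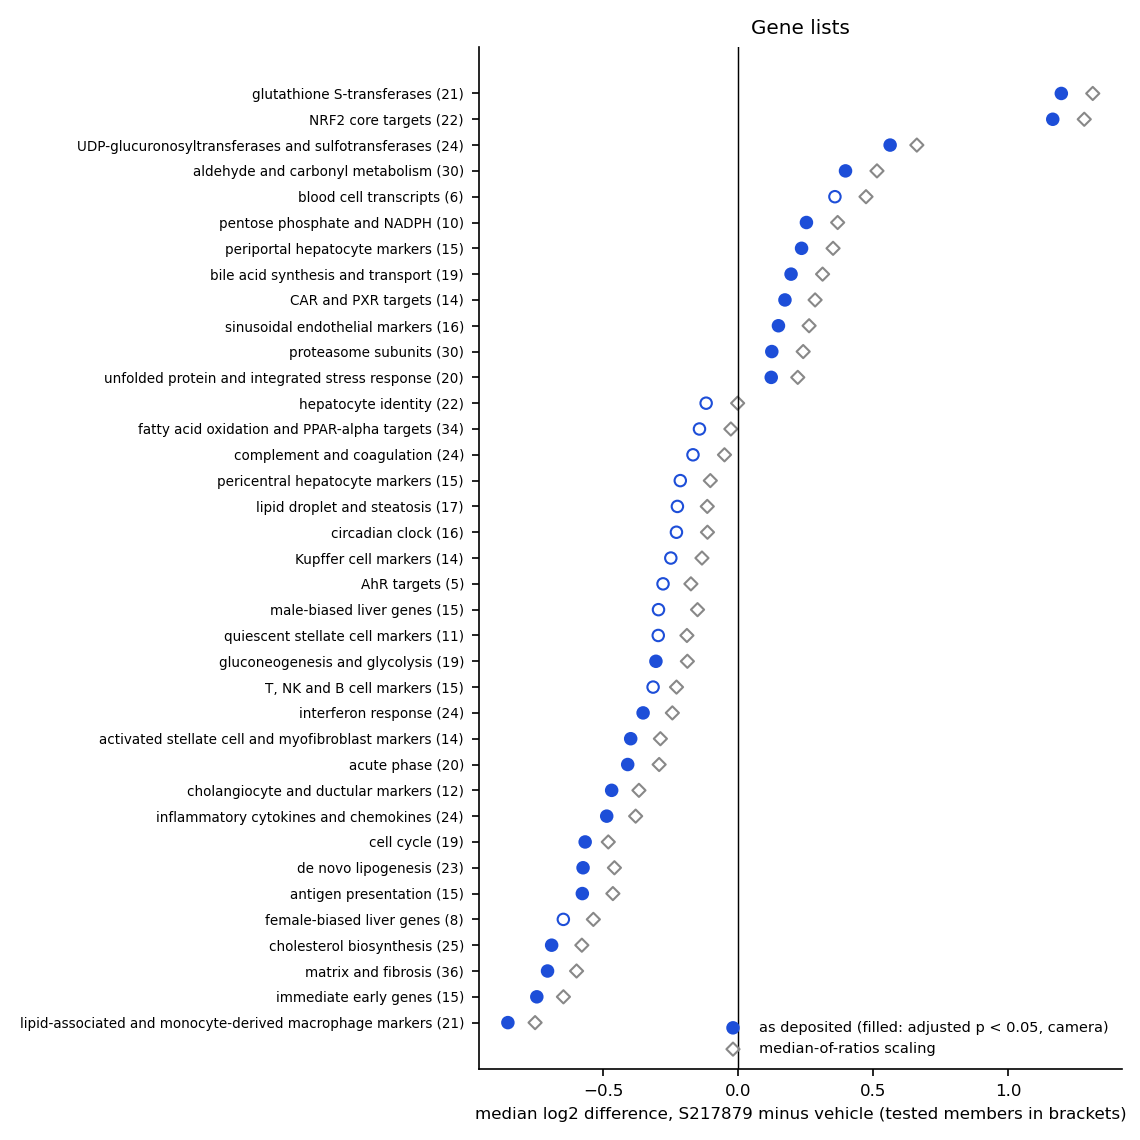
Median log2 difference (S217879 minus vehicle) of the 37 tested lists, as deposited (circles, filled where camera passed with its preset correlation) and with median-of-ratios scaling (diamonds). Glutathione S-transferases (1.20) and NRF2 core targets (1.16) were the highest, and lipid-associated and monocyte-derived macrophage markers (-0.85) the lowest.

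Of 23 de novo lipogenesis genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone, 13 and 4 with median-of-ratios scaling). The lipogenesis list had a median log2 difference of -0.58 (-0.46 relative to all genes), and camera gave adjusted p = 0.0026 (adjusted p = 0.6880 with an estimated correlation). This list call was lost without vehicle replicates 6 and 7 (adjusted p = 0.1290, with 1.40e-04 to 0.7393 over 37 alternatives). Fatty acid synthase, Fasn, fell from 301 ± 104.7 to 128 ± 54.7 TPM, and Me1, the member that rose and also a supplier of NADPH, went from 120 ± 35.2 to 190 ± 50.7 TPM. The neighbouring desaturase genes Fads1, Fads2 and Fads3 lie side by side on chromosome 19 (GRCm38, 10041569 to 10196877 in all). Each of them fell, Fads2 from 1407 ± 312 to 405 ± 138 TPM and Fads3 from 35.7 ± 7.37 to 6.78 ± 1.78 TPM. Mir6993, a microRNA gene model within an intron of Fads1 on the same strand (10191375 to 10191439), fell from 15.5 ± 5.79 to 1.99 ± 1.65 TPM, a value that can hold unspliced Fads1 transcript. Of 25 genes of cholesterol biosynthesis and its control, 0 rose and 21 fell (0 and 23 adjusted over the list alone, 1 and 21 with median-of-ratios scaling). Cholesterol synthesis genes had a median log2 difference of -0.69 (-0.57 relative to all genes), and camera gave adjusted p = 1.87e-08 (adjusted p = 0.4967 with an estimated correlation). Fdps, farnesyl diphosphate synthase, fell from 25.8 ± 8.70 to 6.84 ± 2.52 TPM. Genes of fatty acid oxidation and PPAR-alpha targets went both ways, 2 of 34 higher and 11 lower (2 and 11 adjusted over the list alone, 15 and 13 with median-of-ratios scaling), and did not pass as a list (camera adjusted p = 0.6191). Ehhadh rose from 303 ± 77.6 to 531 ± 56.8 TPM and Acadm from 189 ± 46.3 to 250 ± 27.97 TPM. Cyp4a14 fell from 181 ± 80.0 to 24.5 ± 16.9 TPM and Acot2 from 17.5 ± 3.17 to 5.24 ± 2.09 TPM. Lipid droplet genes did not pass as a list (camera adjusted p = 0.7254), with 2 of 17 higher and 6 lower (2 and 7 adjusted over the list alone). The droplet coat genes Plin2 and Plin4 fell from 438 ± 65.0 to 251 ± 49.1 TPM and from 43.1 ± 7.68 to 28.3 ± 7.61 TPM. Cd36, a fatty acid transporter, rose from 145 ± 28.2 to 209 ± 25.0 TPM, and Fitm1 from 113 ± 30.2 to 185 ± 29.8 TPM. Apoa4, an apolipoprotein gene that rises with liver fat, fell from 2595 ± 508 to 387 ± 197 TPM.

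**Figure D4:**
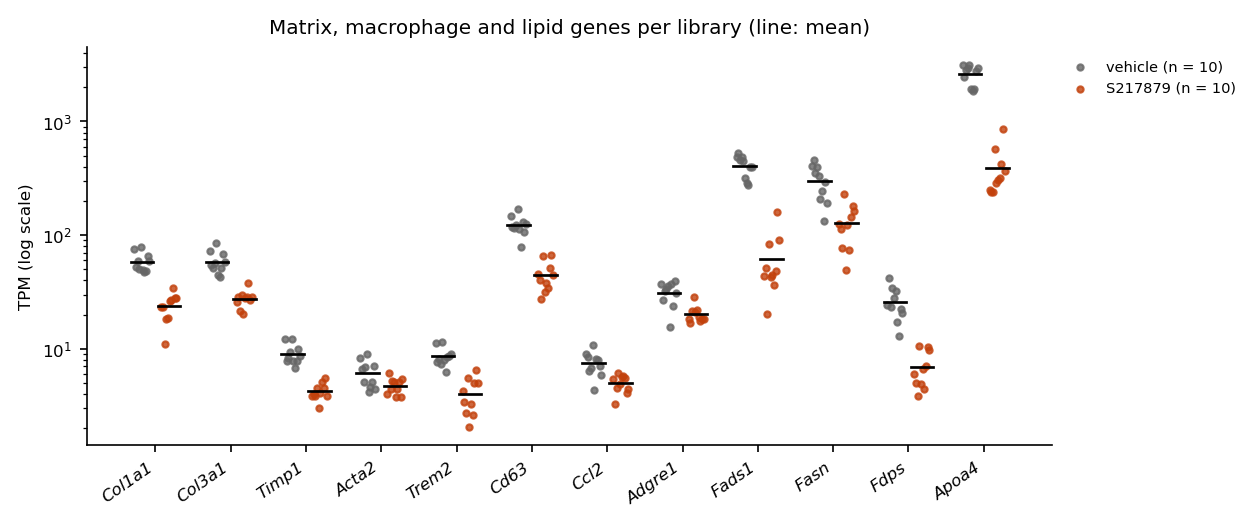
TPM (log axis) of 12 genes of matrix, macrophages, chemokines and lipid metabolism in each of the 20 libraries, with lines at the mean of 10 libraries per group. All 12 were lower in S217879 as deposited, with no overlap between the groups for Col1a1, Col3a1, Timp1, Cd63, Fads1, Fdps and Apoa4, and Acta2 did not pass with median-of-ratios scaling.

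Genes of bile acid synthesis and transport rose in 6 of 19 members and fell in 2 (8 and 3 adjusted over the list alone). The bile acid list had a median log2 difference of 0.20 (0.31 relative to all genes), and camera gave adjusted p = 4.77e-04 (adjusted p = 0.6475 with an estimated correlation). The median was 0.091 without vehicle replicate 6 and 0.010 without vehicle replicates 6 and 7. The call was lost with quantile normalization (median 0.075, adjusted p = 0.3675, with 1.05e-04 to 0.6475 over 37 alternatives). Abcg8, which exports sterols into bile, rose from 119 ± 36.4 to 270 ± 35.04 TPM, and Cyp8b1, the sterol 12-alpha-hydroxylase, from 134 ± 37.9 to 282 ± 70.4 TPM. Slco1a1 fell from 9.64 ± 8.25 to 1.53 ± 0.43 TPM and Abcb4 from 102 ± 20.995 to 67.6 ± 6.62 TPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 47.4 ± 19.04 and 65.8 ± 25.5 TPM (adjusted p = 0.1459, and from 0.0138 to 0.2873 over 33 alternatives, with median-of-ratios and quantile scaling past the threshold). Periportal hepatocyte markers rose in 6 of 15 members and fell in 2 (7 and 2 adjusted over the list alone). Periportal markers had a median log2 difference of 0.23 (0.35 relative to all genes), and camera gave adjusted p = 0.0012 (adjusted p = 0.6475 with an estimated correlation). This median was 0.131 without vehicle replicate 6 and 0.066 without vehicle replicates 6 and 7. With quantile normalization the call was lost (median 0.121, adjusted p = 0.3160, with 2.96e-04 to 0.6475 over 37 alternatives). Cyp2f2 rose from 450 ± 196 to 1903 ± 175 TPM and Etnppl from 10.7 ± 5.19 to 37.9 ± 9.12 TPM. Cdh1 fell from 19.9 ± 4.30 to 10.5 ± 2.65 TPM and Mfsd2a from 102 ± 27.3 to 61.1 ± 21.7 TPM. Pericentral markers did not pass as a list (camera adjusted p = 0.8965, median -0.22 but mean 0.18), with Cyp2a5 and Cyp1a2 rising and 6 of 15 falling (2 and 6 adjusted over the list alone). Oat fell from 409 ± 103 to 203 ± 51.5 TPM and Gulo from 369 ± 73.4 to 210 ± 31.5 TPM. Genes of gluconeogenesis and glycolysis fell in 9 of 19 members with 0 rising (9 and 0 adjusted over the list alone, 9 and 4 with median-of-ratios scaling). Sugar metabolism genes had a median log2 difference of -0.31 (-0.19 relative to all genes), and camera gave adjusted p = 0.0371 (adjusted p = 0.6880 with an estimated correlation). Their median was -0.189 with median-of-ratios scaling. Igfbp1 fell from 72.8 ± 27.5 to 25.1 ± 6.505 TPM and Hk2 from 6.64 ± 1.10 to 3.09 ± 1.08 TPM. The list call was lost without vehicle replicate 6 (adjusted p = 0.0577, with 9.27e-05 to 0.6880 over 37 alternatives).

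Cell cycle genes fell in 13 of 19 members with 0 rising (14 and 0 adjusted over the list alone). The cell cycle list had a median log2 difference of -0.57 (-0.45 relative to all genes), and camera gave adjusted p = 3.73e-06 (adjusted p = 0.4967 with an estimated correlation). With quantile normalization its median was -0.376. The cyclin D1 gene Ccnd1 fell from 37.7 ± 7.48 to 10.97 ± 2.15 TPM and Cdkn1a, which encodes the cell cycle inhibitor p21, from 20.5 ± 4.64 to 9.95 ± 3.30 TPM. Immediate early genes, which respond within minutes to stress or handling of tissue, fell in 10 of 15 members with 0 rising (11 and 0 adjusted over the list alone). The immediate early list had a median log2 difference of -0.75 (-0.63 relative to all genes), and camera gave adjusted p = 8.73e-06 (adjusted p = 0.4154 with an estimated correlation). Egr1 fell from 14.6 ± 4.39 to 3.44 ± 1.24 TPM and Btg2 from 24.0 ± 5.29 to 10.7 ± 2.13 TPM. This fall stands beside those of the matrix, macrophage and cytokine lists in the same animals. Acute phase genes fell in 10 of 20 members and rose in 2 (14 and 2 adjusted over the list alone). The acute phase list had a median log2 difference of -0.41 (-0.29 relative to all genes), and camera gave adjusted p = 0.0126 (adjusted p = 0.6880 with an estimated correlation). Orm2 fell from 119 ± 25.1 to 44.5 ± 16.05 TPM while its neighbour Orm3 rose from 38.5 ± 12.4 to 67.6 ± 18.6 TPM and Saa3 from 4.97 ± 1.67 to 8.90 ± 2.69 TPM. The list call was lost without vehicle replicates 6 and 7 (adjusted p = 0.1287, with 3.19e-05 to 0.7393 over 37 alternatives). Unfolded protein and integrated stress response genes had 4 of 20 higher and 3 lower (4 and 3 adjusted over the list alone, 9 and 3 with median-of-ratios scaling). The stress response list had a median log2 difference of 0.12 (0.24 relative to all genes), and camera gave adjusted p = 0.0436 (adjusted p = 0.6914 with an estimated correlation). The call was kept in 22 of 37 alternatives (adjusted p from 0.0140 to 0.9359). It was lost without each of vehicle replicates 3, 9 and 10 and S217879 replicates 1, 3, 6 and 7 (0.0565 to 0.0999). The median was 0.071 without vehicle replicate 6 and 0.070 without vehicle replicate 7, and it turned to -0.007 when TPM was rescaled without the 4 rRNA-type genes. Trib3 rose from 10.2 ± 3.33 to 18.001 ± 5.77 TPM and Chac1 from 8.25 ± 3.15 to 13.7 ± 2.73 TPM. Gdf15 fell from 25.98 ± 8.29 to 10.97 ± 4.15 TPM and Atf3 from 9.08 ± 1.31 to 3.77 ± 0.82 TPM. Proteasome subunits passed camera (adjusted p = 5.10e-05, but adjusted p = 0.6880 with an estimated correlation) with a median of 0.12 (0.24 relative to all genes), which turned to -0.02 when TPM was rescaled without the 4 rRNA-type genes (0.041 without vehicle replicate 6 and 0.064 without vehicle replicate 7). Of 30 members only Psmb5 was called, rising from 192 ± 42.8 to 258 ± 37.1 TPM (0 adjusted over the list alone), against 29 with median-of-ratios scaling.

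Lists of sex-biased liver genes did not pass (camera adjusted p = 0.9593 each). Of 15 male-biased genes 3 rose and 6 fell (3 and 6 adjusted over the list alone). Ugt2b1 rose from 139 ± 41.9 to 447 ± 97.3 TPM and Cyp2d9 from 584 ± 220 to 1173 ± 141 TPM. Mup3 fell from 2342 ± 772 to 631 ± 398 TPM and Serpina1e from 105.04 ± 72.8 to 23.4 ± 18.6 TPM. Of 8 female-biased genes 3 rose, Cyp2a4 and Cyp2b9 among them, and 4 fell (3 and 4 adjusted over the list alone), Cyp17a1 from 17.9 ± 7.71 to 2.62 ± 1.31 TPM. Circadian clock genes did not pass as a list (camera adjusted p = 0.6251), with 0 of 16 higher and 7 lower (7 lower adjusted over the list alone, 4 higher and 7 lower with median-of-ratios scaling). Per3 fell from 12.7 ± 2.62 to 7.25 ± 1.61 TPM and Bhlhe40 from 62.7 ± 15.4 to 40.5 ± 9.37 TPM. Complement and coagulation genes did not pass (camera adjusted p = 0.36), with 0 of 24 higher and 4 lower (4 lower adjusted over the list alone, 5 higher and 7 lower with median-of-ratios scaling). C8a fell from 238 ± 57.5 to 103 ± 34.5 TPM and C8b from 56.1 ± 18.9 to 22.7 ± 9.60 TPM. Of the adipose, gut and pancreas transcripts only 3 reached the expression minimum, too few for the list test. Cfd rose from 20.8 ± 12.5 to 102 ± 57.4 TPM and Cela1 from 14.8 ± 3.24 to 31.1 ± 11.2 TPM (2 adjusted over the list alone). The fat cell genes Adipoq, Plin1 and Lep reached at most 0.074, 0.034 and 0.013 TPM in any library.

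Among the genes with the largest differences that belong to none of these groups, Slc22a12, a urate transporter, was at 0.025 ± 0.023 TPM in vehicle and 8.85 ± 2.57 TPM in S217879, and Coro6 at 0.42 ± 0.13 and 13.4 ± 4.40 TPM. Lower were Mir6358, a microRNA gene model on chromosome 18 (GRCm38, 76170552 to 76170652), from 7.47 ± 2.12 to 0.046 ± 0.097 TPM, and the adaptor gene Shc2, from 6.29 ± 1.23 to 0.57 ± 0.43 TPM. The receptor gene Ephb2 fell from 4.22 ± 0.69 to 0.56 ± 0.45 TPM, Sprr1a from 13.8 ± 6.25 to 2.54 ± 1.058 TPM and the class I gene H2-Q1 from 60.2 ± 9.34 to 15.95 ± 9.90 TPM. Each of these passed limma with 10 of 10 S217879 animals beyond the vehicle median. Exons of Slc22a12 overlap those of Nrxn2 on the opposite strand, as exons of Apoa4, Cyp2a4, Gclm, Keap1 and Shc2 overlap antisense or divergent noncoding models. Whether the counting used the strand is not given in the sources used here. On the same strand, exons of Gclm overlap the pseudogene model Gm6061 and exons of Col3a1 the microRNA model Gm47302. Strand would not separate reads there.

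In all, 24 of 37 lists passed camera with its preset correlation, 11 upwards and 13 downwards, and 22 did with median-of-ratios scaling. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 20. The sign of the camera test and of the median differed for AhR targets, hepatocyte identity, male-biased genes and pericentral markers, and the sign of the mean and of the median for AhR targets, female-biased genes and pericentral markers.

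Whether animals with higher NRF2 target expression had lower matrix or macrophage expression was examined within each group of 10, over 3 pairs of list scores and so 6 relations (permutation tests, two-sided, 100000 resamples). The macrophage and matrix scores rose together in both groups. In vehicle Pearson's r was 0.97 (p = 2.20e-04, adjusted p = 6.60e-04) and Spearman's rho 0.68 (p = 0.0346, adjusted p = 0.0693), with r = 0.90 without the 2 animals farthest from the median of the macrophage score. In S217879 r was 0.92 (p = 1.90e-04, adjusted p = 6.60e-04) and rho 0.98 (p = 2.00e-05, adjusted p = 1.20e-04), with r = 0.89 without the 2 farthest. Both relations passed with median-of-ratios scaling (r = 0.89 and 0.76), and without Mmp12, the 1 gene in both lists, r was 0.96 and 0.91. The NRF2 score rose with the matrix score in vehicle as deposited (r = 0.86, p = 0.0017, adjusted p = 0.0034, with rho = 0.82, p = 0.0059, adjusted p = 0.0176). It also rose with the macrophage score (r = 0.79, p = 0.0073, adjusted p = 0.0110, with rho = 0.54, p = 0.1153, adjusted p = 0.1730). Neither held without the 2 animals farthest on the NRF2 score (r = 0.61, p = 0.1025, and r = 0.30, p = 0.4693) or with median-of-ratios scaling (r = -0.16 and -0.38). The relation with the macrophage score was also lost without vehicle replicate 6 alone (r = 0.68, adjusted p = 0.0692, with 0.0077 to 0.9050 over 26 alternatives). Both depend on those animals and on the scale of the libraries. In S217879 the NRF2 score had r = -0.01 with the matrix score (p = 0.9790, adjusted p = 0.9790, with rho = 0.14, p = 0.7075, adjusted p = 0.7075) and r = 0.49 without the 2 farthest. Single animals moved this r as well, to 0.66 without S217879 replicate 9 (adjusted p = 0.0523, with 0.0523 to 0.9990 over 26 alternatives) and to -0.275 without S217879 replicate 4. With the macrophage score it had r = -0.03 (p = 0.9334, adjusted p = 0.9790, with rho = 0.20, p = 0.5866, adjusted p = 0.7039). There r was 0.44 without the 2 farthest, and 0.72 (adjusted p = 0.0303, with 0.0303 to 0.9990 over 26 alternatives) without S217879 replicate 9 alone. It was -0.47 without S217879 replicate 4 alone and -0.52 with median-of-ratios scaling. A difference between the groups in these relations was not tested.

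**Figure D5:**
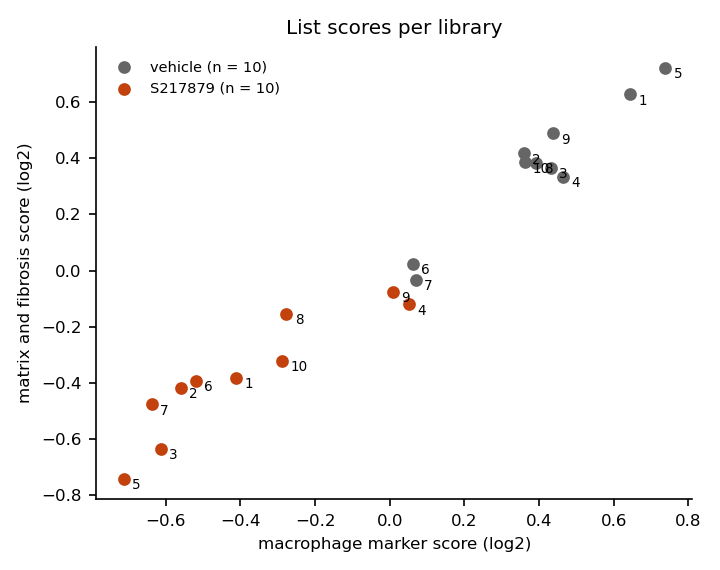
Matrix and fibrosis score against macrophage marker score (mean over list members of log2(TPM + 0.5), centred per gene) for 10 vehicle and 10 S217879 libraries, numbered by replicate. Both scores rise together within each group (r = 0.97 and 0.92), and vehicle replicates 6 and 7 lie lowest among vehicle.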

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

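Of the tests in this part, those on the scale of the libraries, on dilution and on Cyp2a4 were chosen after the result was seen, while the splits of the libraries and the test with immediate early genes were written down before their results. Single libraries far from the other 9 of their group were sought in 154 groups of 10 (40 named genes and 37 list scores, each in both groups). There were 14 where chance alone gives about 7.7, since about 1 in 20 groups is picked out by chance. The measure is the gap to the nearest library as a share of the group's range.

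S217879 replicate 9 made up 7 of the 14. It was the lowest of its group for Gclc (335 TPM against 532 to 899, share 0.468), Srxn1 (102 against 185 to 289, 0.568), Cbr3 (228 against 429 to 809, 0.498), Abcc4 (39.7 against 101 to 177, 0.625), Cyp2a5 (5337 against 7835 to 11434, 0.504) and Cyp1a2 (611 against 1165 to 1846, 0.584), and the highest for the acute phase score (0.72 against -0.54 to -0.09, 0.645). Without it 759 genes were higher, 3381 lower and 400 changed at least 2-fold. Vehicle replicate 6, the library with most rRNA-type TPM, was lowest for the scores of inflammatory cytokines and chemokines (-0.40 against 0.13 to 0.49, 0.599), antigen presentation (-0.41 against 0.03 to 0.53, 0.468) and interferon response (-0.60 against -0.04 to 0.50, 0.506). Its scores for these lists with median-of-ratios scaling were 0.081, 0.125 and -0.098. Vehicle replicate 2 then lay lower in each (-0.005, -0.118 and -0.186), so these gaps depend on the scale of the libraries. Vehicle replicate 3 was highest for T, NK and B cell markers (1.47 against -0.34 to 0.34, 0.627). Vehicle replicate 8 was lowest for Cyp17a1 (3.78 TPM against 11.4 to 31.9, 0.504). S217879 replicate 4 was highest for Adgre1 (28.4 TPM against 16.7 to 22.0, 0.482) and lowest for female-biased liver genes (-0.68 against -0.10 to 0.51, 0.489).

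Chance as the source of the counts was tested with 100 splits of the libraries, the real one included. As many genes on one side as the 813 higher ones came in 3 of 100 splits and as many as the 3151 lower ones in 2, with 3872 in the highest other split; 370 genes changed at least 2-fold in the real split alone (1 of 100), with 73 in the highest other. These shares argue against chance for each of these counts of genes. The split with 3872 kept 8 vehicle libraries together with 2 of S217879, so it follows the treatment in large part; 94 of the 99 other splits called no gene. As many lists as the 24 came in 3 of 100 splits. This is the same share as for the 813 higher genes and argues against chance for the count of lists. The other splits still called a median of 15 lists and up to 25, so the margin is narrow. Single list calls of camera with its preset correlation are weak evidence by themselves.

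More genes were lower than higher as deposited (3151 against 813). Different shares of the 4 rRNA-type genes are not the cause, since TPM rescaled without them moved the median log2 difference away from 0, to -0.253 (SE 0.029). The 20% of genes with the highest mean TPM lay 0.223 (SE 0.055) above the 20% with the lowest, so genes did not all shift alike. This test cannot exclude a single scale shift as the cause of the imbalance. With median-of-ratios scaling the medians of the highest and lowest 20% still differed (0.134 and -0.111), while 50.5% of the calls were lower. A shift as the whole cause or a part of it stays open. Abundant transcripts that rose, such as Gstm1, may take TPM from all others, and TPM holds no outside reference. A change of the whole liver transcriptome with treatment was not tested.

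The matrix, stellate and macrophage lists fell together. For the matrix and fibrosis list a scale shift is excluded as the whole cause, since its median stayed at -0.599 (SE of the score 0.061) with median-of-ratios scaling. The activated stellate and macrophage medians were -0.289 and -0.753 with this scaling, but were not tested in this way. A larger share of hepatocyte RNA that dilutes all other cells would lower endothelial markers alike. The endothelial score differed from the matrix score by 0.870 (SE 0.061) between the groups, which argues against such a dilution as the only change. Dilution as a part of the fall stays open, since endothelial markers may have changed by themselves. Different handling of the tissue cannot be told apart from treatment: with the immediate early gene score as a covariate the matrix difference went from -0.64 (SE 0.06) to -0.400 (SE 0.129), past the bound of -0.3 set beforehand by less than its error, and that score itself differs between the groups by -0.58 (SE 0.07). Whether fewer cells or less transcript per cell may underlie the fall was not tested.

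Cyp2a4 was 59.7-fold higher on the log2(TPM + 0.5) scale, next to its paralog Cyp2a5, which rose to 9436 TPM. Reads of Cyp2a5 assigned to Cyp2a4 at a fixed rate would keep their ratio, and as the whole cause this is excluded, since the log2 ratio rose by 1.756 (SE 0.282; p = 4.00e-05, permutation test). Such reads may still make up a part of the Cyp2a4 value, because how reads shared between such copies were assigned is not given. The ratios of the groups overlapped, with the highest vehicle ratio (6.23%) above the lowest S217879 ratio (5.92%). An induction of Cyp2a4 itself is a hypothesis that these values leave open.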

How the results depend on the processing

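Chosen after seeing the data were rescaling without the 4 rRNA-type genes, leaving out vehicle replicates 6 and 7 together, an estimated correlation after rescaling, and median-of-ratios scaling for relations. The direction of the large changes was stable, but the number of genes called depends on how the libraries are scaled. Leaving out each library in turn gave 709 to 877 genes higher, 2637 to 5194 lower, 352 to 400 changed at least 2-fold, 22 to 24 lists and 3 to 5 relations. The 5194 came without vehicle replicate 6, the library with the highest rRNA-type share, and no other single library moved a count of genes by over 1.5 times. Genes higher went from 813 to 3536 with quantile normalization, 3561 with median-of-ratios scaling and 1446 without the 20 genes of highest mean TPM. Genes lower went from 3151 to 1642 with a minimum of 5 TPM, where fewer genes are tested, to 7279 without those 20 genes and to 8023 with array weights. They went to 8576 rescaled without the 4 rRNA-type genes and to 7307 without vehicle replicates 6 and 7. A Wilcoxon rank-sum test per gene gave 833 higher and 3234 lower. Genes changed at least 2-fold went from 370 to 228 with the minimum of 5 TPM. Relations past the threshold went from 4 to 2 with quantile normalization, with Spearman in place of Pearson, without the 2 farthest animals, and with median-of-ratios scaling. In vehicle, the relation of NRF2 core targets with macrophage markers changed sign with quantile normalization (-0.148) and median-of-ratios scaling (-0.379), and that with matrix and fibrosis with median-of-ratios scaling (-0.161). In S217879 the relation of NRF2 core targets with lipid-associated and monocyte-derived macrophage markers ran from -0.473 without replicate 4 to 0.724 without replicate 9 when single libraries were left out, and was -0.521 with median-of-ratios scaling. That with matrix and fibrosis ran from -0.275 without replicate 4 to 0.662 without replicate 9. Lists called went from 24 to 0 with an estimated correlation in camera, which leaves the medians as they are but not the calls (adjusted p from 0.0555 to 0.6914, with 3 lists at an unadjusted p under 0.05 and 20 called by fry). The medians of the lists so lost were, upwards, NRF2 1.164, glutathione transferases 1.196, pentose phosphate 0.252, CAR and PXR 0.173, endothelial 0.148, bile acid 0.195, unfolded protein 0.122, proteasome 0.124, periportal 0.234, glucuronosyl- and sulfotransferases 0.562, carbonyl 0.397. Downwards they were matrix -0.706, activated stellate -0.399, macrophage -0.853, cytokines -0.487, antigen presentation -0.578, interferon -0.353, cholangiocyte -0.469, lipogenesis -0.575, cholesterol -0.691, gluconeogenesis -0.305, cell cycle -0.567, acute phase -0.410, immediate early -0.746. With an estimated correlation after median-of-ratios scaling 0 lists were called (adjusted p from 0.1615 to 0.7500, with 8 lists at an unadjusted p under 0.05). The medians were then NRF2 1.281, glutathione transferases 1.312, pentose phosphate 0.368, CAR and PXR 0.284, endothelial 0.262, bile acid 0.312, unfolded protein 0.220, proteasome 0.240, periportal 0.351, glucuronosyl- and sulfotransferases 0.661, carbonyl 0.513 upwards. Downwards they were matrix -0.599, activated stellate -0.289, macrophage -0.753, cytokines -0.380, antigen presentation -0.465, interferon -0.244, cholangiocyte -0.368, lipogenesis -0.459, cholesterol -0.580, gluconeogenesis -0.189, cell cycle -0.482, acute phase -0.293, immediate early -0.648. With it after rescaling without the 4 rRNA-type genes 3 lists were called, NRF2 core targets, glutathione S-transferases, and UDP-glucuronosyltransferases and sulfotransferases. The others (adjusted p from 0.0630 to 0.7393) had medians of pentose phosphate 0.120, CAR and PXR 0.038, endothelial 0.011, bile acid 0.051, unfolded protein -0.007, proteasome -0.019, periportal 0.091, carbonyl 0.253 among those called upwards. Among those called downwards they had matrix -0.858, activated stellate -0.543, macrophage -1.014, cytokines -0.634, antigen presentation -0.723, interferon -0.493, cholangiocyte -0.615, lipogenesis -0.719, cholesterol -0.838, gluconeogenesis -0.449, cell cycle -0.727, acute phase -0.554, immediate early -0.906. The test fry ended 6 calls (CAR and PXR, endothelial, bile acid, unfolded protein, proteasome, periportal) and added those of AhR targets (median -0.279, upwards by fry) and Kupffer cell markers (-0.250). A minimum of 0.1 TPM added blood cell transcripts (0.289, adjusted p = 0.0412). Adipose, gut and pancreas transcripts, with too few members for a test at 1 TPM, were also called upwards there (0.253, adjusted p = 0.0227) and with no filter (median -0.006, adjusted p = 0.0283), and a minimum of 5 TPM ended CAR and PXR (0.149) and unfolded protein (0.136). Quantile normalization ended CAR and PXR 0.113, bile acid 0.075, unfolded protein 0.054, periportal 0.121. It added, all downwards, Kupffer cell markers (-0.312), hepatocyte identity (-0.170, against an upward camera direction as deposited), fatty acid oxidation (-0.181) and complement (-0.259). Median-of-ratios scaling ended CAR and PXR (0.284) and unfolded protein (0.220), and leaving out mitochondrially encoded genes ended unfolded protein (0.141). Leaving out the 20 genes of highest mean TPM ended interferon -0.434, cholangiocyte -0.560, lipogenesis -0.780, gluconeogenesis -0.377, acute phase -0.482. The same 5 calls ended when TPM was rescaled without the 4 rRNA-type genes (interferon -0.493, cholangiocyte -0.615, lipogenesis -0.719, gluconeogenesis -0.449, acute phase -0.554), with complement added (-0.312). They also ended without vehicle replicates 6 and 7 (interferon -0.450, cholangiocyte -0.576, lipogenesis -0.722, gluconeogenesis -0.429, acute phase -0.534). Array weights ended cholangiocyte -0.544, lipogenesis -0.692, gluconeogenesis -0.397 and added complement (-0.333). Leaving out single libraries ended a list call in 12 cases, for cholangiocyte, gluconeogenesis or unfolded protein. Over all libraries left out in turn, the cholangiocyte median ran from -0.528 to -0.389. Those of gluconeogenesis and unfolded protein ran from -0.378 to -0.245 and from 0.070 to 0.144. Leaving out single libraries also ended the call of a named gene in 24 cases, all but 1 of them for Acta2 or Epcam, the other for Apoa2. Apart from the scale of the libraries and the smaller number of genes or animals, the cause was not tested. No paired analysis was possible because the groups share no animal numbers. Depth is unknown, so no limit from read counts can be given.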

Other observations

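Apart from Hmox1 and Cfd, which the fixed rule named, the genes of this part were chosen after their values were seen. Ftl1 and Fth1 are also members of the NRF2 core target list fixed beforehand. The gene groups were chosen, and tested, after their values were seen. Catalase, Cat, the peroxisomal enzyme that breaks down hydrogen peroxide, rose from 1401 ± 345 to 3609 ± 318 TPM (log2 difference 1.41, adjusted p = 6.91e-10 by limma, n = 10 each), and the iron storage genes Ftl1 and Fth1 rose from 4056 ± 736 to 8595 ± 1335 TPM and from 3384 ± 595 to 6336 ± 681 TPM. Slc48a1, a heme transporter, rose from 46.8 ± 8.82 to 136 ± 19.1 TPM while Hmox1 did not pass the test. Among single genes, the glycine decarboxylase gene Gldc rose from 56.6 ± 14.3 to 144 ± 15.1 TPM, Abat from 67.2 ± 17.8 to 148 ± 12.2 TPM and Ddc from 16.7 ± 3.22 to 48.5 ± 10.5 TPM. Ppp1r3c, a regulator of glycogen synthesis, rose from 14.2 ± 5.89 to 46.7 ± 17.2 TPM.

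Egfr, the epidermal growth factor receptor, fell from 41.9 ± 19.8 to 20.5 ± 16.7 TPM (adjusted p = 0.0162), Tnfrsf12a, the receptor for TWEAK, from 38.9 ± 5.96 to 14.3 ± 3.66 TPM, Gas6 from 138 ± 23.5 to 72.0 ± 24.6 TPM, Igfbp2 from 467 ± 159 to 186 ± 52.9 TPM, Anxa2 from 64.6 ± 10.9 to 27.5 ± 7.64 TPM and Anxa5 from 360 ± 69.1 to 173 ± 39.1 TPM. The 10 annexin genes did not pass as a group (1 rose and 5 fell, camera adjusted p = 0.2514). Maff, of the small MAF family whose proteins pair with NRF2, fell from 22.0 ± 5.03 to 9.54 ± 1.93 TPM. Slc10a2, the apical bile acid transporter of bile ducts and ileum, fell from 23.2 ± 6.81 to 7.47 ± 3.64 TPM. Of 12 desaturase and elongase genes 6 fell and 1 rose (median log2 difference -0.67, camera adjusted p = 0.0020 over 11 groups chosen after their values were seen; adjusted p = 0.4195 with an estimated correlation), with Elovl2 falling from 288 ± 49.1 to 147 ± 33.6 TPM. Of 11 class I genes of the H2-Q and H2-T regions, close paralogs of each other, 9 fell and 0 rose (median -0.72, camera adjusted p = 2.33e-04; adjusted p = 0.4195 with an estimated correlation).

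Groups of abundant housekeeping transcripts show what the scale does. Of 50 cytosolic ribosomal protein genes 3 rose as deposited and 44 with median-of-ratios scaling (medians 0.19 and 0.31), of 36 NADH dehydrogenase subunits 6 and 33 (medians 0.21 and 0.33), and of 13 mitochondrially encoded mRNAs 1 rose and 1 fell as deposited and 11 rose after scaling (medians 0.31 and 0.43). Camera passed for each as deposited (adjusted p = 2.57e-08, 6.02e-08 and 3.03e-04) but with an estimated correlation gave adjusted p = 0.4195 for all of them. Cfd rose 5.17-fold on the log2(TPM + 0.5) scale (log2 difference 2.371, and 1.534 with array weights) with Adipoq at no more than 0.074 TPM in any library.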
